A study of Homo sapiens with 4 samples.

How the data were processed

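Human U266 and K562 cells were grown in RPMI-1640 with fetal bovine serum, and total RNA was extracted with Trizol and purified on an RNeasy column, per the labels' protocols. Biotin-labelled cRNA was prepared by the standard Affymetrix procedure, per the labels, and the probe annotation used here names the Affymetrix Human Gene ST array in its comment line. The 4 groups were U266 with vehicle or 15 µM atovaquone for 2 h and K562 with vehicle or 20 µM atovaquone for 5 h, with 1 array per group, as the labels give them. The deposited values are the authors' processed array intensity for each probe set on a linear scale, without negative values. The software, background correction, normalisation and summary of probes that the authors used are not given in the sources used here. The lowest value is exactly 1 on every array, held by 82, 70, 91 and 81 probe sets on the U266 vehicle, U266 atovaquone, K562 vehicle and K562 atovaquone arrays. Array medians of 339, 340, 314 and 319 lay close together, and whether the arrays had been normalised to each other is not stated. Centring on the median ratio removes any change shared by most genes. The array's own probe design also limits the values, since 1 probe set may mix signal from several transcripts.

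Of 33252 probe sets, 21214 were listed in the annotation, 19460 of them with 1 gene symbol and 1754 with several, and 12038 were unlisted. Of those with 1 symbol, 19429 matched a current gene by Entrez identifier, and 0 symbols needed an update. Only probe sets with 1 symbol were used as genes, which gave 18417 genes, 769 of them with several probe sets. Because of this rule HSPA1A, HSPA1B and other genes that share a probe set have no value. A gene with several probe sets was represented by the one with the highest mean log2 intensity over the 4 arrays. MT2A had 3 probe sets whose U266 log2 ratios differed in size, at 0.29, 0.88 and 0.29.

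Intensities were put on the log2 scale. Each array's floor was its 40th percentile over listed probe sets, which took the place of a definition by control probes, because control probe sets are not marked as such in the tables used here. The floors were intensities of 331, 324, 305 and 306, and lower values were raised to them. A gene at or above the floor on both arrays of a comparison counted as measured, which left 10731 genes in U266 and 10755 in K562. Log2 ratios, atovaquone minus vehicle, were centred on the median ratio of measured probe sets, which removed −0.0096 in U266 and −0.0048 in K562. A gene below the floor on 1 array has only a bound, written as "at least N-fold". Such bounds of at least 2-fold were 10 higher and 1 lower in U266 and 8 higher and 0 lower in K562. With 1 array per group there was no replicate, so no test was run, and genes were counted at a fixed size of 2-fold, with 1.5-fold for members of lists.

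The 30 gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. For each list, the median log2 ratio of its measured genes was placed among the medians of 10000 random lists of the same size, drawn in 20 bins of mean intensity, when at least 5 genes were measured. A list outside percentiles 2.5 to 97.5 is said to stand apart, as a description of these arrays. The named genes were the 10 highest and 10 lowest ratios per line, the 3 highest bounds per direction, and STAT3 targets at least 1.5-fold different. They also included SOCS3, BCL3, MCL1, JUNB, MYC and PIM1 whatever their value, and up to 4 members of each other list by size of ratio, of which the text names some. Between lines they were genes at least 2-fold different the same way, up to 10 per direction, and up to 5 in opposite directions. Between vehicle arrays they were 4 markers per list, and CD38 was added after its value was seen. The overlap expected by chance was the product of the gene numbers of both lists divided by the genes measured on all 4 arrays.

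The calculation was tested on simulated data. The noise had the SD of the difference in log2 ratio between 2 probe sets of 1 gene. That is wider than the SD of single probe sets given in the results. In the U266 simulation with 10744 genes, 100% of 50 genes raised 3-fold and 66% of 50 lowered 3-fold were counted as at least 2-fold. In the K562 simulation with 10809 genes these shares were 100% and 64%. Lowered genes were missed mainly because they dropped under the floor, since 70% and 66% of them stayed measured on both arrays. Of genes set to 1.5-fold, 2% passed 2-fold in either direction in U266 and 0% in K562. In either line 0 unchanged genes passed 2-fold. That was fixed by the setting, since the simulated log2 noise had an SD of 0.15 in U266 and 0.17 in K562. The noise left out the spread between cultures. Random lists of unchanged genes lay outside the central 95% in 5.5% of cases in U266 and 8.0% in K562. Low shares followed from the setting, since noise was drawn independently for each gene and the lists at random. They do not cover lists whose genes vary together.

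Alternatives were deposited values with no centring, quantile normalisation, loess within each comparison with a span of 0.3, no floor, floors at the 20th and 60th percentiles, the median over a gene's probe sets, and a pseudocount of 16. Thresholds of 1.5-fold and 3-fold, a requirement of one sign for all probe sets of a gene, and the mean of a list in place of its median were also run. Members at their bound, lists without shared members and counts without small RNA genes were added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.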

Results

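Gene expression was measured on 4 arrays, each hybridised with labelled RNA from a human leukaemia or myeloma line exposed to atovaquone or to its vehicle. U266 is a multiple myeloma line that makes and responds to IL-6, a cytokine that signals through STAT3. K562 is a chronic myeloid leukaemia line that carries BCR-ABL1, signals through STAT5 and has erythroid features. Atovaquone is an antimalarial hydroxynaphthoquinone that blocks complex III of the respiratory chain. U266 cells received vehicle (DMSO) or 15 µM atovaquone for 2 h, and K562 cells received vehicle or 20 µM atovaquone for 5 h. There was 1 array in each group and so no replicate, which limits the precision of every value below. No test or p-value was computed, and each ratio describes a pair of arrays. Deposited intensities covered 33252 probe sets, with array medians of 339, 340, 314 and 319 for U266 vehicle, U266 atovaquone, K562 vehicle and K562 atovaquone. Rank correlation across probe sets was 0.992 between the U266 arrays and 0.991 between the K562 arrays, against 0.797 between the atovaquone arrays of the 2 lines.

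The vehicle arrays of the lines carried the genes of their cell types. Of 12 plasma cell markers measured on at least 1 vehicle array, 11 were at least 2-fold higher in U266 and 0 in K562, with a median log2 difference of at least 2.82, since some members have only a bound. JCHAIN, the joining chain of secreted immunoglobulin, was at least 35.6-fold higher in U266, and TNFRSF17, the BCMA receptor of plasma cells, at least 13.9-fold. The IL-6 receptor gene IL6R was 11.6-fold higher in U266, and PRDM1, which encodes the plasma cell regulator Blimp-1, at least 10.0-fold. CD38, named after its value was seen, was the exception, with a log2 difference of −0.73. Of 13 erythroid and megakaryocytic markers measured, 11 were at least 2-fold higher in K562, with a median log2 difference of −2.05 or lower for the same reason. The embryonic globin genes HBZ and HBE1 were 17.9-fold and 9.85-fold higher in K562, the Rh-associated glycoprotein gene RHAG at least 11.4-fold, and GATA1, the erythroid transcription factor, at least 9.08-fold. The list of T cell, fibroblast and epithelial markers had 11 members measured on at least 1 vehicle array and a median of −0.33 or lower. Of its members, KRT18, KRT8 and EPCAM, all epithelial genes, were 7.94-fold, 5.95-fold and at least 5.55-fold higher in K562, and KRT19 at least 1.66-fold. Across 9480 genes measured on both vehicle arrays, 755 were at least 2-fold higher in U266 and 660 in K562.

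The comparison of atovaquone with vehicle in U266 asks which genes differ after a short exposure. By list median, heat shock and immediate early genes had the highest ratios of atovaquone to vehicle. JUN, a subunit of the AP-1 transcription factor, was 10.4-fold higher with atovaquone, with an intensity of 3977 against 385. DUSP1, a phosphatase that inactivates MAP kinases, was 9.04-fold higher, with an intensity of 3665 against 408. DNAJB1, an HSP40 co-chaperone, was 4.69-fold higher, and SOCS3, the feedback inhibitor of cytokine signalling and a STAT3 target, had a log2 ratio of 1.30. Of 10731 genes measured on both U266 arrays, 35 were at least 2-fold higher with atovaquone and 0 were at least 2-fold lower. Of the 35, 5 were on the immediate early list, 5 on the ATF4 list and 3 on the heat shock list, and 19 were on none of the 30 lists. Both counts depend on the floor, with 73 higher and 20 lower with no floor, 6 lower with it at the 20th percentile and 15 higher at the 60th. In simulated U266 data 66% of genes lowered 3-fold were counted as lower, most of the others having dropped under the floor. The simulated genes were drawn from above the 60th percentile of vehicle intensity, so that share does not cover dimmer genes.

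The heat shock protein list, made of targets of the transcription factor HSF1, had a median log2 ratio of 0.47 in U266, at percentile 100 of matched random lists. All 14 measured members lay above 0, and 5 of them were at least 1.5-fold higher and 0 lower. DNAJB1 had a log2 ratio of 2.23, the HSP70 co-chaperone BAG3 1.95, the HSP110 gene HSPH1 1.32 and the small heat shock protein gene HSPB1 0.64. SERPINH1, a collagen chaperone of the endoplasmic reticulum that is not on the list, was 5.30-fold higher. The immediate early list had a median of 0.36, also at percentile 100. Of its 20 measured members 13 lay above 0, and 8 were at least 1.5-fold higher and 0 lower. Beside JUN and DUSP1, the zinc finger transcription factor EGR1 was 3.79-fold higher and ZFP36, which promotes the decay of AU-rich mRNAs, had a log2 ratio of 1.27. The orphan nuclear receptor genes NR4A2 and NR4A3 were below the floor on the vehicle array and were at least 14.7-fold and at least 7.68-fold higher with atovaquone. SAT1, which encodes a polyamine acetyltransferase, was at least 8.73-fold higher. Bounds move with the floor by construction. JUN, DUSP1 and EGR1 lay little above the floor on the vehicle array and fell under it with the floor at the 60th percentile. That left lower bounds of 2.57, 2.45 and 1.18 in place of log2 ratios of 3.38, 3.18 and 1.92.

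The other genes among the 10 highest in U266 were SNORD14E, a small nucleolar RNA gene within HSPA8, at 6.63-fold, the small GTPase gene RHOB at 5.45-fold, RGS1, a regulator of G protein signalling, at 4.72-fold, and PPP1R15A, the GADD34 phosphatase subunit that reverses eIF2α phosphorylation, at 3.85-fold. On the low side the ratios were smaller. ZC3HAV1, an antiviral zinc finger protein gene, was 1.91-fold lower with atovaquone and had the lowest ratio of the 10731 genes. UNC119B, HYLS1, SLC10A5 and ZNF253 followed, with log2 ratios of −0.72, −0.70, −0.68 and −0.65. LINC00341 and the ubiquitin ligase subunit gene SKP2 both stood at −0.62, as did FP248, and FICD and DOLK stood at −0.61 and −0.60. MIR142, a microRNA gene of blood cells, was below the floor with atovaquone and at least 4.31-fold lower. Values of genes near the floor depend on where it is set. With the floor at each array's 60th percentile, FP248, HYLS1, SLC10A5 and UNC119B lay under it on both arrays and had no ratio. FICD and DOLK were under it with atovaquone, with upper bounds of −0.17 and −0.50. On the high side RHOB, SNORD14E and PPP1R15A were under that floor on the vehicle array, with lower bounds of 1.53, 1.85 and 1.48.

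STAT3 target genes in U266 had a median log2 ratio of 0.09, at percentile 99.9. Of 20 measured members, 15 lay above 0, 4 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. Those 4 were SOCS3 at 1.30, MYC at 0.84, and the transcriptional repressor genes BCL6 and NFIL3, both at 0.81. JUNB stood at 0.41, PIM1 at 0.12, BCL3 at 0.04 and the survival gene MCL1 at −0.08. With the floor at the 60th percentile none of the 4 stayed measured on both arrays. SOCS3, MYC and NFIL3 were under it on the vehicle array, with lower bounds of 0.46, 0.03 and 0.53. BCL6 lay under it on both arrays and had no ratio.

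The list of ATF4 and integrated stress response genes had a U266 median of 0.07, at percentile 99.96, with 5 of 40 measured members at least 1.5-fold higher and 0 lower. These included PPP1R15A at 1.95, the mTORC1 inhibitor gene DDIT4 at 1.29, DDIT3, which encodes the stress transcription factor CHOP, at 1.22, and CTH, an enzyme of cysteine synthesis, at 1.11. Hypoxia and HIF1 targets had a median of 0.09 at percentile 99.3. On the high side were DDIT4, ANKRD37 at 0.82 (at least 0.37 with the floor at the 60th percentile) and BHLHE40 at 0.76. The glucose transporter gene SLC2A3 stood at −0.32. Without the members also on the ATF4 or immediate early lists, the hypoxia median was 0.07 at percentile 95.9, inside the central 95% of random lists. Cytosolic ribosomal protein genes had a median of 0.07 at percentile 99.2 with 0 members at least 1.5-fold higher, led by RPL10A at 0.24. Plasma cell markers had a median of 0.08 at percentile 98.6, also with 0 members at least 1.5-fold higher, and IL6 stood at 0.46, PRDM1 at 0.28 and MZB1 at −0.24. The ribosomal list fell inside the central 95% after quantile normalisation, with a median of 0.03, and the plasma cell list did so with no floor and with the floor at the 20th percentile.

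The remaining lists in U266 lay inside the central 95% of matched random lists or had too few genes for a percentile. Among lists tied to signalling, medians were 0.07 for STAT5 targets, 0.07 for NF-kB targets, 0.05 for interferon-stimulated genes, 0.04 for short-lived transcripts, −0.02 for p53 targets and −0.05 for apoptosis regulators. Single members of these lists were higher, such as the STAT5 target DUSP5 at 0.83 and the pro-apoptotic BH3-only genes BCL2L11 at 0.95 and PMAIP1 at 0.67. With the floor at the 60th percentile PMAIP1 had only a lower bound of 0.02. Among metabolic lists, medians were 0.04 for glycolysis enzymes, −0.02 for complex III subunits, 0.04 for other respiratory chain and ATP synthase subunits, −0.0083 for pyrimidine and nucleotide synthesis, 0.03 for cholesterol synthesis and 0.03 for autophagy and lysosome genes. Of 10 complex III genes measured, UQCRB was the single one at least 1.5-fold higher, at 1.17 (at least 0.48 with the floor at the 60th percentile). GLA, which encodes a lysosomal galactosidase, stood at 1.49. Among stress and defence lists, medians were −0.02 for chaperones of the endoplasmic reticulum, 0.02 for NRF2 antioxidant genes and 0.06 for metallothioneins. Among proliferation lists, medians were 0.06 for mitosis, −0.03 for S phase, −0.02 for histone genes and 0.05 for MYC targets and ribosome biogenesis. Medians were 0.0042 for erythroid markers and 0.04 for T cell, fibroblast and epithelial markers. Lists with fewer than 5 measured genes were given no percentile, and their medians were −0.14 for TXNIP and glucose-sensing targets and 0.01 for xenobiotic response genes, each over 3 genes. The mean had the opposite sign to the median for complex III subunits at 0.09, p53 targets at 0.04, apoptosis regulators at 0.03 and erythroid markers at −0.0096.

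The comparison in K562 asks the same of a higher dose and a longer exposure. Targets of ATF4, the transcription factor of the integrated stress response, were higher with atovaquone, and genes of mitosis, ribosome biogenesis, histones and heat shock were slightly lower. DDIT4 was 10.4-fold higher, with an intensity of 5728 against 552, and DDIT3 was 4.27-fold higher. CTH was 3.84-fold higher and SESN2, a sestrin that restrains mTORC1, 3.80-fold. Of 10755 genes measured on both K562 arrays, 28 were at least 2-fold higher with atovaquone and 14 were at least 2-fold lower. Of the 28, 13 were on the ATF4 list. Both counts depend on the floor, with 77 higher and 31 lower with no floor, 53 higher with it at the 20th percentile and 6 lower at the 60th.

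The ATF4 and integrated stress response list had a K562 median log2 ratio of 0.62, at percentile 100 of matched random lists. Of 36 measured members, 34 lay above 0, 19 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. TRIB3, a pseudokinase induced by CHOP, was 3.29-fold higher, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, 3.24-fold, and ASNS, asparagine synthetase, 2.83-fold. CHAC1, a glutathione-degrading enzyme, was below the floor on the vehicle array and at least 10.5-fold higher. ATF3, a stress transcription factor, and TSC22D3, the glucocorticoid-induced leucine zipper gene, were likewise below the floor, at least 3.57-fold and at least 3.78-fold higher. TUBE1, which encodes epsilon tubulin, HERPUD1, a gene of degradation at the endoplasmic reticulum, and CCDC71L completed the 10 highest, at 2.87-fold, 2.79-fold and 2.75-fold. With the floor at the 60th percentile TUBE1 and TSC22D3 had lower bounds of 0.84 and 0.83 in log2 ratio.

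Targets of p53 had a median of 0.18 in K562 at percentile 99.97, with 13 of 18 measured members above 0, 4 at least 1.5-fold higher and 0 lower. Those 4 were SESN2 at 1.93, the TRAIL receptor gene TNFRSF10B at 1.01, the stress cytokine gene GDF15 at 0.93 and PMAIP1 at 0.69. SESN2 and GDF15 are also on the ATF4 list, and neither line carries normal p53. Without members shared with the ATF4 and immediate early lists, the p53 median was 0.11 at percentile 97.6. CD3E, a T cell marker, stood at 0.33 and lay under the floor on both arrays when that was set at the 60th percentile. T cell, fibroblast and epithelial markers had a median of 0.12 at percentile 97.8, with 0 of 11 members at least 1.5-fold higher. That list stayed outside the central 95% under 2 of 8 other settings of normalisation, floor and probe sets, and its median was −0.03 with the floor at the 60th percentile.

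Heat shock protein genes had a median of −0.15 in K562 at percentile 0.080. Of 14 measured members 3 lay above 0, 1 was at least 1.5-fold lower and 0 were at least 1.5-fold higher. DNAJB1 was that member, 1.78-fold lower, and CHORDC1 stood at −0.52, BAG3 at −0.48 and DNAJA1 at −0.33. Mitosis genes had a median of −0.16 at percentile 0.030, with 3 of 24 members above 0 and 0 at least 1.5-fold lower, led by the kinesin genes KIF23 at −0.49 and KIF11 at −0.42 and by cyclin B, CCNB1, at −0.42. MYC targets and ribosome biogenesis genes had a median of −0.15 at percentile 0.010, with 6 of 22 members above 0 and 1 at least 1.5-fold lower, NIP7 at −0.59. The ribosome assembly gene RRS1 stood at −0.50 and NOP16 at −0.48. Histone genes had a median of −0.12 at percentile 0.34, with 2 of 13 members at least 1.5-fold lower, the linker histone H1-3 at −0.95 and H2BC8 at −0.67.

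The other lists below the central 95% in K562 did not stay there under every setting. STAT3 targets had a median of −0.10 at percentile 2.4, with 9 of 19 measured members above 0, 1 at least 1.5-fold higher and 2 lower. CEBPB, a bZIP transcription factor gene that is also on the ATF4 list, stood at 1.18, the immediate early gene IER3 at −0.74 and the adhesion molecule gene ICAM1 at −0.62. PIM1 stood at 0.40, JUNB at −0.34, MCL1 at −0.21, BCL3 at −0.15, SOCS3 at −0.10 and MYC at 0.02. Immediate early genes had a median of −0.11 at percentile 1.6, with 9 of 20 members above 0, 0 at least 1.5-fold higher and 2 lower, IER3 and KLF10 at −0.72. JUN stood at 0.45 and KLF6 at 0.51. The list of TXNIP and glucose-sensing targets of MondoA had a median of −0.37 over 5 genes at percentile 0.020, yet TXNIP itself, the arrestin that limits glucose uptake, stood at 0.26. Its lower members were KLF10, the arrestin gene ARRDC4 at −0.38 and PFKFB3, which makes an activator of glycolysis, at −0.37. Under a floor at the 60th percentile KLF10 was under it on both arrays and had no ratio, and JUN had a lower bound of 0.03. IER3, ARRDC4 and PFKFB3 had upper bounds of −0.45, −0.04 and −0.02. The STAT3 median was 0.02 with that floor, the TXNIP median 0.07 without KLF10, ARRDC4 and PFKFB3, and the immediate early median −0.0051 with no floor. The immediate early list also lay inside the central 95% after quantile and loess normalisation.

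Of the 14 genes at least 2-fold lower, 5 were small nucleolar RNA genes, among them SNORD14E at 2.85-fold, SNORD50B at 2.49-fold and SNORD52 at 2.26-fold. PPP1R10, a nuclear regulatory subunit of protein phosphatase 1, was 2.83-fold lower on its 3 probe sets, which hold identical values. PCF11, a factor of transcript cleavage and transcription termination, was 2.45-fold lower and JMJD6, a nuclear hydroxylase, 2.31-fold. The olfactory receptor gene OR2B6 was 2.31-fold lower, the histone gene H2AC4 2.25-fold, the variant U1 small nuclear RNA gene RNVU1-15 2.24-fold and NRROS 2.16-fold. Without small RNA genes, 8 genes were at least 2-fold lower. With the floor at the 60th percentile several of these genes were under it with atovaquone and had only upper bounds that no longer reached 2-fold. These were −0.48 for SNORD14E, −0.58 for SNORD50B, −0.40 for RNVU1-15, −0.67 for JMJD6 and −0.93 for H2AC4.

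The remaining lists in K562 lay inside the central 95% of matched random lists or had too few genes for a percentile. Among lists tied to signalling, medians were −0.06 for STAT5 targets, −0.03 for NF-kB targets, −0.07 for interferon-stimulated genes, −0.0004 for short-lived transcripts and −0.06 for apoptosis regulators. The STAT5 target ID1 stood at −0.77, with only an upper bound of −0.21 with the floor at the 60th percentile. Among metabolic lists, medians were 0.02 for hypoxia targets, −0.02 for glycolysis enzymes, 0.07 for complex III subunits, 0.06 for other respiratory chain subunits, −0.02 for pyrimidine and nucleotide synthesis, 0.07 for cholesterol synthesis and 0.03 for autophagy and lysosome genes. VEGFA, a hypoxia target that is also on the ATF4 list, stood at 1.42. The sterol regulator gene INSIG1 stood at 0.64 and the pyrimidine synthesis gene DHODH at −0.37. With the floor at the 60th percentile DHODH lay under it on both arrays and had no ratio. Among stress lists, medians were −0.02 for chaperones of the endoplasmic reticulum, 0.06 for NRF2 antioxidant genes and 0.03 for metallothioneins. The cystine transporter gene SLC7A11, on both the NRF2 and the ATF4 list, stood at 1.32, and the endoplasmic reticulum list held HERPUD1 at 1.48, XBP1 at 0.63, the chaperone gene HSPA5 at 0.45 and SDF2L1 at −0.39. Medians were 0.01 for S phase genes, 0.07 for ribosomal proteins, −0.02 for plasma cell markers and 0.06 for erythroid markers, and 0.14 over 4 genes for xenobiotic response, which had no percentile. The mean had the opposite sign to the median for endoplasmic reticulum chaperones at 0.10, S phase genes at −0.01, apoptosis regulators at 0.03 and plasma cell markers at 0.06.

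**Figure D1:**
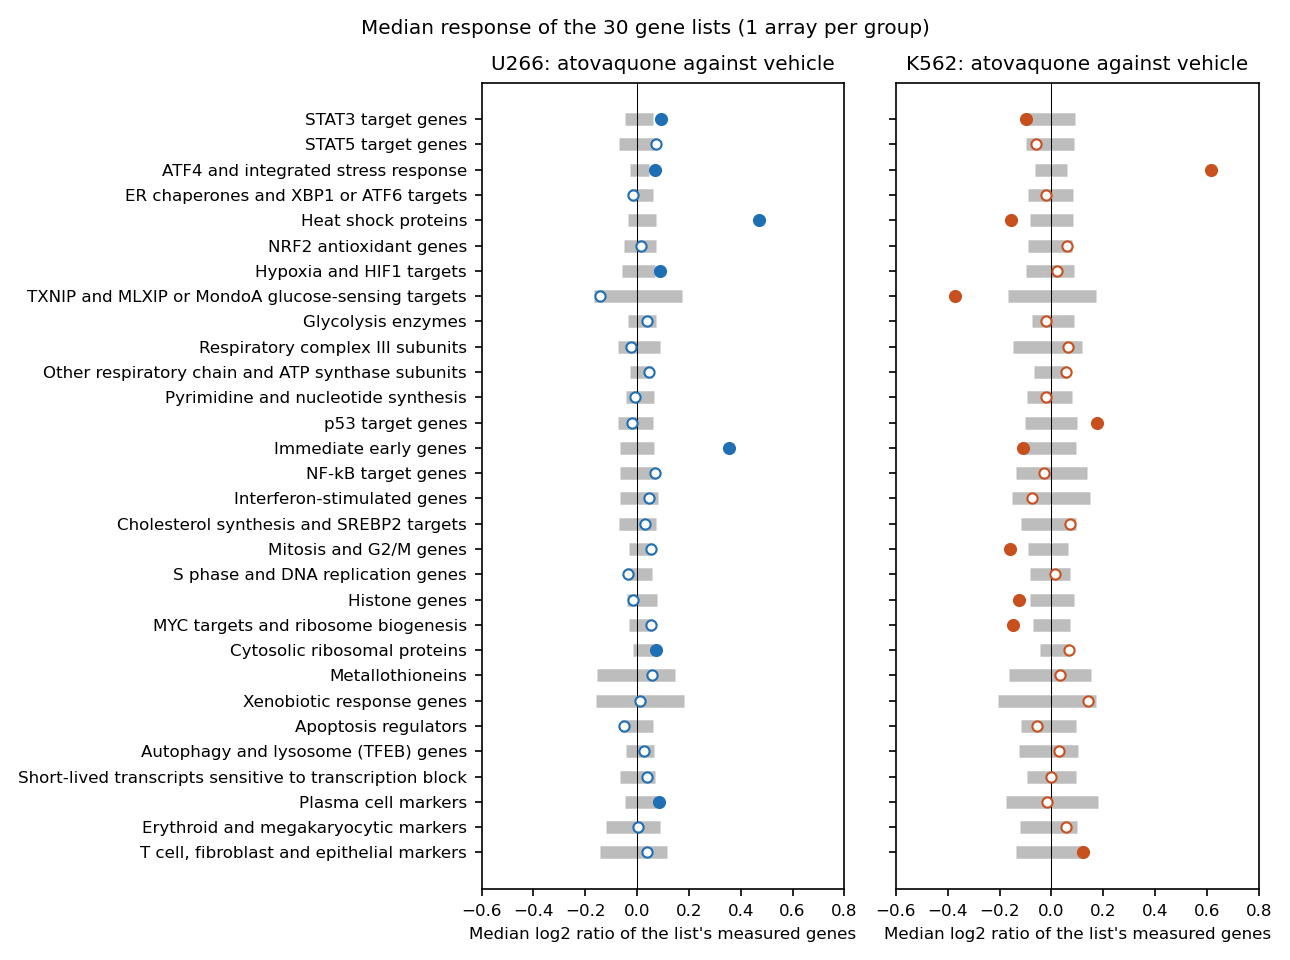
Median log2 ratio, atovaquone against vehicle, of the measured genes of each of the 30 lists in U266 (left) and K562 (right). Grey bars span the central 95% of 10000 random lists matched on expression, filled points lie outside it and open points inside it or have fewer than 5 genes; the ATF4 list stands at 0.07 in U266 and 0.62 in K562, and the heat shock list at 0.47 and −0.15.

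Over both lines, 57 list comparisons had a percentile and 17 lay outside the central 95%. By chance 2.85 would be so for independent lists whose genes also vary independently. The random lists do not cover lists whose genes vary together, so 17 against 2.85 is a description and not a test. The spread of ratios was narrow, with a central 95% of log2 ratios of −0.28 to 0.34 in U266 and −0.42 to 0.48 in K562. The only measure of technical spread within a pair of arrays came from genes with several probe sets, whose log2 ratios had an SD of 0.11 over 330 genes in U266 and 0.12 over 347 genes in K562. That SD leaves out the spread between cultures.

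Set side by side, the lines had different genes at the top. Across 9220 genes measured on all 4 arrays, the log2 ratios of U266 and K562 had a Pearson correlation of 0.09 and a Spearman correlation of 0.10. These are across genes, which are not independent replicates. Of these genes, 3 were at least 2-fold higher in both lines, DDIT4, DDIT3 and CTH, where 0.064 would be expected for independent lists of 27 and 22 genes. DDIT4 was 2.44-fold higher in U266 and 10.4-fold in K562, DDIT3 2.32-fold and 4.27-fold, and CTH 2.16-fold and 3.84-fold. With genes below the floor on a vehicle array at their bound, ATF3, SAT1 and CHAC1 also passed 2-fold in both lines. ATF3 was at least 5.95-fold higher in U266 and at least 3.57-fold in K562, SAT1 at least 8.73-fold and 2.56-fold, and CHAC1 2.01-fold and at least 10.5-fold. With the floor at the 60th percentile CTH in U266 and ATF3 in K562 had lower bounds of 0.90 and 0.75 in log2 ratio. SNORD14E and SNORD14C were the 2 genes at least 2-fold higher in U266 and at least 2-fold lower in K562, where 0.032 would be expected for independent genes. Both lie within the same host gene, HSPA8, so they do not count as 2 independent genes. SNORD14C had log2 ratios of 1.68 in U266 and −1.09 in K562, and SNORD14E of 2.73 and −1.51.

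Of 36 ATF4 list members measured in both lines, 33 had a higher ratio in K562 than in U266, and the 4 at least 1.5-fold higher in U266 were among the 19 in K562. TRIB3 stood at −0.07 in U266 and 1.72 in K562, PCK2 at 0.0092 and 1.70, and ASNS was 1.18-fold and 2.83-fold higher. PPP1R15A went the other way, at 1.95 in U266 and 0.77 in K562. All 14 heat shock list members had a higher ratio in U266, with DNAJB1 at 2.23 and −0.83 and BAG3 at 1.95 and −0.48. Of 18 immediate early genes measured in both lines, 17 had a higher ratio in U266, with JUN at 3.38 and 0.45, DUSP1 at 3.18 and 0.02, and EGR1 at 1.92 and −0.25. Of 18 STAT3 targets, 15 had a higher ratio in U266, with SOCS3 at 1.30 and −0.10 and MYC at 0.84 and 0.02. Cell line, dose and exposure time all differed between these comparisons and cannot be told apart.

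**Figure D2:**
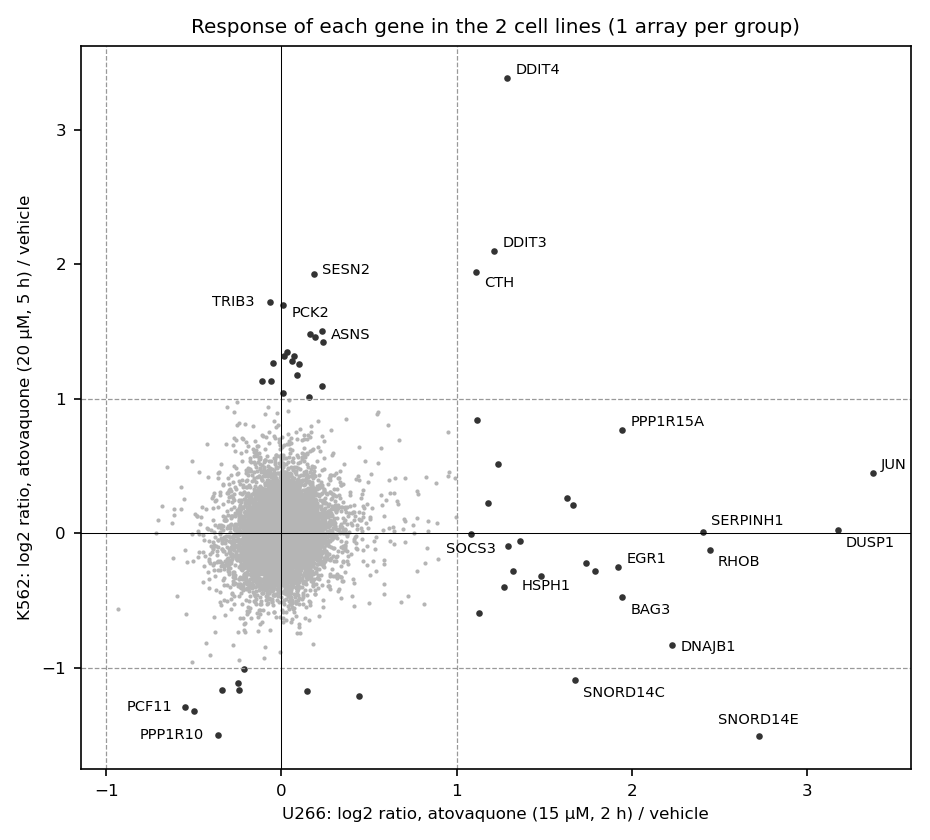
Log2 ratio of atovaquone to vehicle for each of 9220 genes measured on all 4 arrays, U266 on the horizontal and K562 on the vertical axis. Dark points are at least 2-fold higher or lower in either line, dashed lines mark 2-fold, and DDIT4, DDIT3 and CTH are the 3 genes in the upper right corner.

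**Figure D3:**
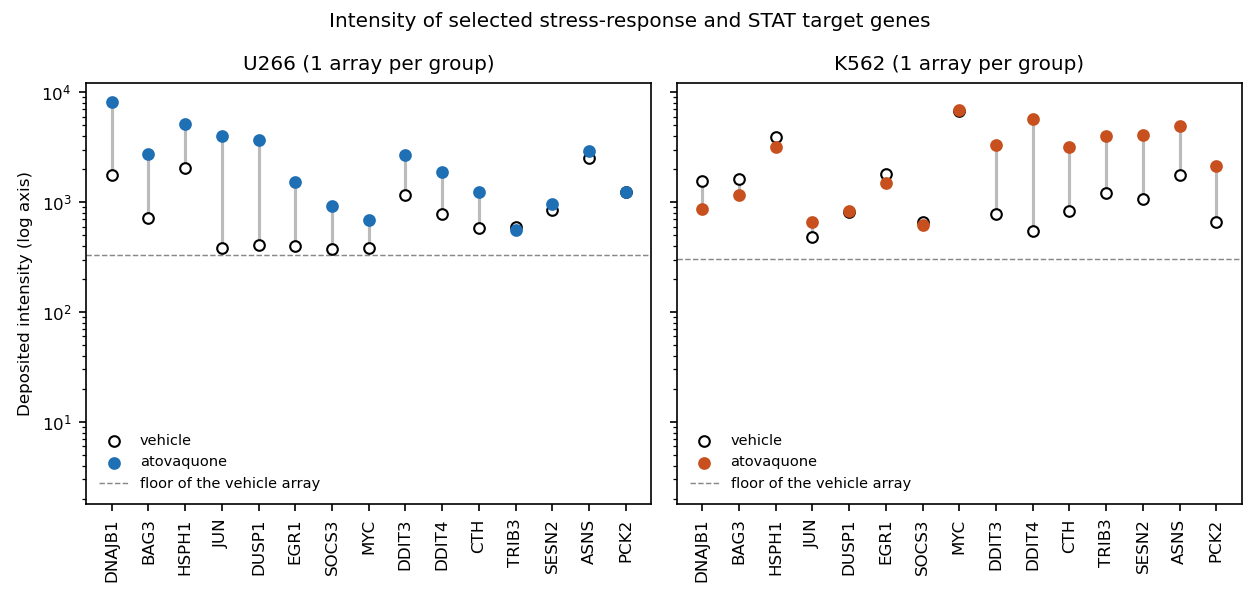
Deposited intensity on a log axis of selected heat shock, immediate early, STAT3 target and ATF4 target genes on the vehicle (open) and atovaquone (filled) array of each line, 1 array per group, with the floor of the vehicle array as a dashed line. DNAJB1 was at 1764 and 8221 in U266 and at 1554 and 872 in K562, and DDIT4 at 784 and 1901 in U266 and at 552 and 5728 in K562.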

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

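The tests of normalisation and of line, dose and time in this part were chosen after the result was seen, and the others before it. None of the differences between lines below was itself tested, because each line had 1 array per group.

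Several results went opposite ways in the 2 lines. The U266 minus K562 difference was 4.24 in log2 ratio for SNORD14E and 2.77 for SNORD14C. For list medians it was 0.62 for heat shock proteins, 0.47 for immediate early genes and 0.19 for STAT3 targets. The opposite direction of the STAT3 list depends on the floor, since its K562 median was 0.0168 with the floor at the 60th percentile. The K562 immediate early median was −0.0070 with the floor at the 20th percentile and −0.0051 with no floor, and the list lay inside the random range under 5 of 8 settings. The SNORD14E ratio in K562 had only an upper bound of −0.48 with the floor at the 60th percentile.

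Heat shock genes were higher with atovaquone in U266 and lower in K562. The criterion for a trend left by normalisation was that a list median would turn sign or move inside the random range in one line. Under quantile and loess normalisation the U266 median stayed at 0.42 or more and the K562 median at −0.16 or less. These medians argue against such a trend as the whole cause. They also lay outside the random range each time. That was largely settled beforehand, since random lists matched on intensity share a trend with intensity. The same 14 members were measured in both lines and all 14 had the higher ratio in U266, so different members do not account for it. The difference of 0.62 may come from the line, the dose or the time, which cannot be told apart because all of them vary together.

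ATF4 targets were higher in K562 than in U266. Over members measured in both lines 91.7% had a higher ratio in K562, so the pattern does not come from different members. The median difference was at least 0.56 under the same normalisations, which argues against a trend in intensity as the whole cause. The difference of 0.55 over shared members could follow the line, the dose or the time of exposure, and these cannot be told apart in this design.

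SNORD14C and SNORD14E lie in introns of HSPA8, the constitutive HSP70 gene, whose own log2 ratio was 0.14 in U266 and −0.07 in K562. A difference in the yield of small RNA between arrays would shift other small nucleolar RNA genes alike. Their median was 0.21 in U266, with an SD of 0.29 over 100 genes, against a SNORD14 mean of 2.20, and −0.0164 in K562, with an SD of 0.36 over 97 genes, against −1.30. Both SNORD14 genes were picked for being at least 2-fold different in each line, which alone places them far from these medians. The comparison was thus settled by the choice of genes and cannot decide on yield. Signal from the host's primary transcript may contribute, but across other small nucleolar RNA genes within a host the correlation with the host was −0.12 in U266 (bootstrap 95% interval −0.29 to 0.08) and −0.0055 in K562 (−0.25 to 0.22), and these intervals keep it open.

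Signals also appeared in probe sets outside the gene comparisons. Of unlisted probe sets whose number lies below the first listed one, 18 of 2126 measured were at least 2-fold higher with atovaquone in U266. In K562 this held for 7 of 2144, and 0 were lower in either line. Of the other unlisted probe sets, 4 of 1855 measured were at least 2-fold higher and 25 lower in U266. In K562, 7 of 1811 were higher and 21 lower. Of probe sets with several symbols, 9 of 1153 measured were at least 2-fold higher and 0 lower in U266. In K562, 2 of 1073 were higher and 5 lower. Among genes, 35 of 10731 were higher and 0 lower in U266, and 28 of 10755 higher and 14 lower in K562.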

How the results depend on the processing

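The alternatives that remove shared list members, set members below the floor at their bound or leave out small RNA genes were chosen after seeing the data, and the others before. Values with no centring, loess within each comparison, a pseudocount of 16 and the requirement of one sign over probe sets moved no count, median or correlation beyond its limit. A median within its limit can still change whether its list stands apart. Under loess, STAT5 targets in U266 came to stand apart, at percentile 98.5. Immediate early genes and T cell, fibroblast and epithelial markers in K562 no longer did, at percentiles 2.6 and 97.1. Over all alternatives, 721 values that answer a comparison were within their limits, 54 moved beyond them and 4 reversed, and for named genes these numbers were 2040, 83 and 5. Where values moved, the cause was not tested beyond what each setting does. A fit of line plus treatment over the 4 arrays was not run, since it would take different doses and times as 1 treatment and leave 1 residual degree of freedom. Leaving out probe sets by the ending of their identifier was not run, since the identifiers are plain numbers.

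With 1.5-fold in place of 2-fold, 92 genes were higher and 10 lower in U266, 153 higher and 75 lower in K562, 8 higher in both lines and 4 higher in U266 and lower in K562. At 3-fold, 16 genes were higher in U266 and 6 higher and 0 lower in K562, with 0 higher in both and 0 in opposite directions. With no floor, 73 genes were at least 2-fold higher and 20 lower in U266, 77 higher and 31 lower in K562, 10 higher in both and 5 lower in both, and the Spearman correlation was 0.0503. With the floor at the 20th percentile, 6 genes were lower in U266, 53 higher in K562 and 7 higher in both. With the floor at the 60th percentile, 15 genes were higher in U266, 6 lower in K562, 1 higher in both and 1 in opposite directions, and the Pearson correlation was 0.12. Without small RNA genes, 8 were lower in K562 and 0 lay in opposite directions.

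The immediate early median in U266 was 0.53 at the 20th percentile, 0.45 at the 60th, 0.52 with no floor and 0.46 with members at their bound, and in K562 it was −0.0070 at the 20th percentile and −0.0051 with no floor. At the 60th percentile the K562 medians of STAT3 targets, TXNIP targets and T cell, fibroblast and epithelial markers reversed to 0.0168, 0.0721 and −0.0316, and U266 medians were 0.14 for erythroid markers and 0.19 for NF-kB targets. Members under that floor drop out of a list, so these medians cover fewer genes. The TXNIP list lost KLF10, ARRDC4 and PFKFB3, its lower members, and had too few genes left for a percentile. Its change of sign thus reflects the loss of these members. With members at their bound the K562 STAT3 median reversed to 0.0161 and the U266 median of short-lived transcripts was 0.12, and with no floor the K562 one was 0.11. Quantile normalisation gave 0.0329 for ribosomal proteins in U266. Means in place of medians were 0.89 in K562 and 0.22 in U266 for ATF4 targets, 0.69 for heat shock, 0.70 for immediate early genes, 0.24 for STAT3 targets, 0.31 for STAT5 targets, 0.36 for short-lived transcripts, 0.18 for hypoxia targets, 0.11 for autophagy, 0.0935 for complex III and 0.0314 for apoptosis in U266. In K562 they were 0.10 for endoplasmic reticulum chaperones, 0.22 for hypoxia targets, 0.18 for NRF2 genes and 0.28 for p53 targets.

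Of the lists that stood apart, STAT3, ATF4, heat shock, hypoxia and immediate early genes in U266 did so under all 8 settings of normalisation, floor and probe sets, of which 1, no centring, shifts all genes alike and cannot alter a percentile. ATF4, p53, heat shock, mitosis, histone and ribosome biogenesis genes in K562 did too. The K562 lists of STAT3 targets and of immediate early genes did so under 5 and 3 of the 8. Lists that stood apart under an alternative alone were STAT5 targets, NF-kB targets, interferon-stimulated and mitosis genes in U266 and short-lived transcripts and erythroid markers in K562. Of the values of named genes, 88 moved beyond the spread between probe sets, 76 of them at the floor of the 60th percentile, where dim genes are raised to the floor. The named genes counted as reversed were FP248, HYLS1, SLC10A5 and UNC119B in U266 and KLF10 in K562. They lay under that floor on both arrays, so their values of 0.0006 and 0.0207 come from the floors alone and are not ratios. Values of genes near the floor are the least certain, and background itself was not measured.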

Other observations

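The lists in this part were drawn up after the data were seen, and the test on tRNA synthetases was written down before its own result was known. Small nucleolar RNA genes as a class were higher with atovaquone in U266, with a median log2 ratio of 0.21 over 102 measured genes, above all matched random lists at percentile 100. Of these genes 87 lay above 0, 15 were at least 1.5-fold higher and 0 were at least 1.5-fold lower. SNORD59B, within the ATP synthase gene ATP5F1B, stood at 1.18 and SNORD58A, within the ribosomal protein gene RPL17, at 1.00. In K562 the median was −0.04 over 99 genes at percentile 3.9, with 0 genes at least 1.5-fold higher and 10 lower, among them SNORD12C at −0.96 and SNORD75 at −0.90. Small RNA is captured unevenly by RNA columns, so these class medians are given as values of single arrays.

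A wider list of histone genes, picked by a pattern in their symbols, was drawn up after the lower values of the fixed histone list and of H2AC4 were seen. The pattern need not cover every histone gene, and H4C14 and H4C15 hold identical values. This wider list contains members of the fixed list and is not independent of it. Its K562 median was −0.19 over 56 measured genes at percentile 0, with 8 at least 1.5-fold lower and 0 higher. In U266 the median was −0.02 over 56 genes at percentile 3.1, with 0 genes past 1.5-fold in either direction. Genes of transcript cleavage and termination did not stand apart as a list, with a median of −0.04 over 18 genes in K562 at percentile 24.7, although PPP1R10 and PCF11 were among the lowest genes of that line. The same list had a median of 0.0008 in U266 at percentile 36.5, and PCF11 stood at −0.55 there.

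Aminoacyl-tRNA synthetase genes charge tRNAs in the cytosol or in mitochondria, and several cytosolic ones are ATF4 targets. The hypothesis was that the higher values in K562 were specific to the cytosolic enzymes. Cytosolic synthetase genes had a K562 median of 0.19 over 19 genes at percentile 100, with AARS1 at 0.57 and CARS1 at 0.53. Mitochondrial ones had a median of 0.03 over 16 genes at percentile 73.9, although WARS2 stood at 0.59. The difference of 0.16 lay between the 0.1 set as counting against the hypothesis and the 0.3 set as being in its favour, so it stays open. In U266 the medians were 0.06 over 19 cytosolic genes at percentile 95.9 and −0.03 over 15 mitochondrial genes, both inside the central 95%. Several cytosolic synthetases are also members of the ATF4 list, so their values are not independent of it.

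Unlisted probe sets with numbers below the first listed one had a median log2 ratio of 0.08 over 2126 measured probe sets in U266, against 0.01 for listed probe sets matched on brightness. In K562 their median was 0.06 over 2144 probe sets. The other unlisted probe sets had medians of 0.02 over 1855 in U266 and 0.09 over 1811 in K562, so a higher K562 median was not particular to the low numbers.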
